A study of Gallus gallus with 6 samples.

How the data were processed

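RNA from the eyelids of 6 Lindian chickens was sequenced, 3 with black and 3 with light-yellow eyelids, all killed at 30 weeks of age. Per the labels' protocols, total RNA was extracted with TRIzol and made into libraries with a NEBNext Ultra RNA kit, 1 library per bird, so replicates are separate birds. The table of the whole series holds 1 FPKM column per library, computed by the authors before deposit, with identifiers in the first column. Per the submitters' processing notes, the tools were TopHat, HTSeq 0.6.1, Cufflinks 2.1.1 and DESeq 1.18.0, with no role or order stated. The genome build, the annotation release and whether counting used strand are not given in the sources used here. Without strand, reads of overlapping or antisense loci cannot be told apart, and this also applies to the non-Ensembl loci. Each column was matched to its bird by the sample description, and 0 columns were left unmatched. Colour and bird number came from the sample titles.

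The identifiers could not be turned into gene names. The gene name table used here, for the assembly GRCg7b, gives an Ensembl identifier for 0 of its 25635 entries, so none of the 15508 Ensembl identifiers could be looked up in it. The 17 gene lists fixed before the data were examined (melanin synthesis, melanocyte regulators, carotenoid handling, keratinocytes, muscle, leukocytes, handling stress and others) therefore could not be matched to loci, and no list was tested. The rule for named genes had asked for up to 12 genes with a symbol in each direction. In its place, 2 identifiers per direction are named: those with the largest log2 difference among loci past the threshold or, where fewer than 2 passed, those with the smallest p. No coordinates are given for the same reason.

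Loci with a mean of at least 1 FPKM over all 6 libraries were kept, which left 13253 and set aside 4527, of which 330 were listed at 0 in every library. Values were transformed to log2(FPKM + 1) and compared, black minus light-yellow, with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend, two-sided, Benjamini-Hochberg adjustment over the 13253 loci). Adding 1 understates the change of low loci. FPKM is relative to the library total, so a few abundant loci can shift all others. The median log2 difference over loci was 0.065 as deposited and 0.0062 after median-of-ratios rescaling, and the share of loci higher in black eyelids was 63.0% and 51.3%. Both also moved with single libraries: as deposited they were -0.0073 and 49.2% without light-yellow bird 1, and 0.107 and 67.4% without light-yellow bird 3.

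Depth, here the read total behind each library's FPKM scale, was recovered from the values. Between 2 libraries, the FPKM ratio of a locus is a ratio of whole numbers times a constant, and this constant was taken from loci at low levels and refined on 6482 to 6575 loci per library. Whole reads were found for 17221 loci with a value above 0 in at least 2 libraries, which covered 99.8% of all values above 0. For 99.3% of the loci used to set the scale, the implied length was whole within 0.02 bases, and the counts of 142 loci that shared a common factor were restored from it. The recovered reads came to between 99.5% and 99.6% of the library totals implied by the authors' scaling, 17116783 to 20621850. The median was 533 reads per tested locus and library. A few loci whose counts share an undetected factor are recovered too low. Whether a unit is a read or a read pair is not given in the sources used here. Between any 2 libraries the chi-square of the recovered reads was at least 44.8 per degree of freedom, more than counting noise alone would give. This does not show that the birds are separate, which rests on the labels.

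Because FPKM values are not counts, the test on recovered reads (limma's voom) is an alternative, chosen after seeing the data. Other alternatives changed the pseudocount (0.1 and 0.5), the filter (none, and a mean of 5 FPKM), the scaling (median-of-ratios, quantile), the weights, the trend, the threshold, and the libraries (each left out in turn). A fit with the bird number as a block was also run, since the numbers 1 to 3 occur in both colours. Nothing in the labels says that the numbers pair the birds. Comparisons of single values per library used exact permutation of the 6 libraries. The recovery and the test were tested on simulated data: counts drawn from the real means, spreads and library sizes, with 200 loci changed. The changed loci were drawn only from those above a floor of reads and an FPKM floor higher than the test's. Reads came back exactly for 99.1% of the recovered loci. Among 13210 simulated loci tested, limma made 5 false calls and called 94% of loci changed by 4 on the log2 scale. The simulation draws loci independently and holds no variation shared between loci. Its calling rates hold for 200 changed loci and would be lower with few. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used for the recovery.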

Results

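The eyelids of 6 Lindian chickens, a Chinese native breed, were compared by sequencing of messenger RNA from eyelid tissue. The birds were 30 weeks old. In 3 birds the eyelid was black and in the other 3 it was light-yellow, and each bird gave 1 library. The question set by the design was which transcripts differ between pigmented and pale eyelids. The table listed 17780 loci, of which 15508 had Ensembl chicken identifiers and 2272 had identifiers of another kind, such as Novel02050, and are called non-Ensembl loci here. It paired no identifier with a gene name or a position, so the loci are given by identifier only, and at most 2 are named in each direction. The read total behind each library's scale was recovered from the steps between FPKM values (fragments per kilobase of locus, scaled to the library total). This total, called depth here, was 20621850, 17116783 and 19626098 reads for black-eyelid birds 1, 2 and 3. It was 17820824, 20503061 and 19426492 reads for light-yellow birds 1, 2 and 3. Nearly all of it lay in the listed loci, so it need not equal the reads sequenced or mapped. Between 16506 and 16970 loci had a value above 0 in a library.

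Between the colours, 4 of 13253 tested loci differed, and all 4 were higher in black eyelids (limma on log2(FPKM + 1), Benjamini-Hochberg adjusted p under 0.05). In the other direction limma called 0 loci, against 1 in its voom fit to the recovered reads with library totals and 0 with median-of-ratios size factors, alternatives chosen after seeing the data. Among the 4, 1 had an Ensembl identifier and 3 were non-Ensembl loci. At an unadjusted p under 0.05 there were 344 loci, 200 higher and 144 lower in black eyelids, against 663 expected by chance alone. This shortfall depended on the fit. There were 2389 such loci with array quality weights and 1790 in the voom fit with quality weights. Without black-eyelid bird 1 there were 1223, and with the first component of the variation within colours as a covariate 880. The other alternatives gave 204 to 496. Black-eyelid bird 1 lay with light-yellow birds 2 and 3 on the first principal component (below). The count of 1223 without it can therefore hold variation that crosses the colours. Which libraries the quality weights favoured is not given here. The mean difference was 2-fold or more on the log2(FPKM + 1) scale for 95 loci toward black and for 47 toward light-yellow. Of these, 36 and 23 had no overlap between the birds of the 2 colours. The same count of 59 loci ranged from 24 to 398 in the 9 other ways to split the 6 libraries into 3 and 3, with a median of 40.

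**Figure D1:**
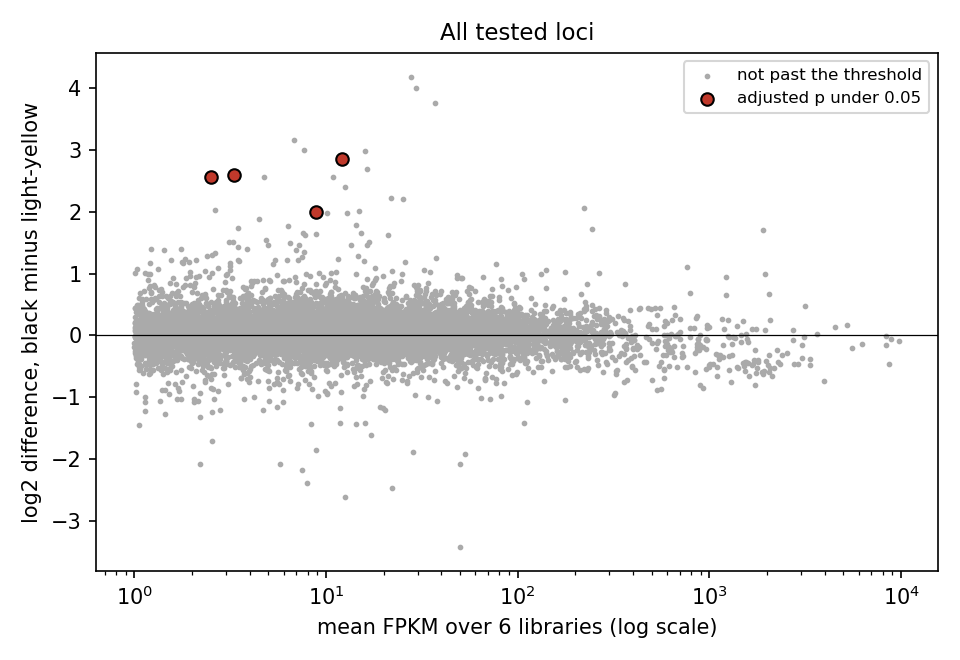
Each point is a tested locus, with its mean FPKM over 6 libraries on a log axis and its log2 difference, black minus light-yellow, on the log2(FPKM + 1) scale. The 4 loci with an adjusted p under 0.05 (larger points) all lie above 0, and 6 loci with larger differences toward black did not pass.

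The order of the loci that passed depended on the scale. ENSGALG00000014634 had the largest difference on the log2(FPKM + 1) scale. With pseudocounts of 0.5 and 0.1, and in the voom fit with library totals, a locus with 0 reads in light-yellow eyelids (below) came first and Novel02050 next. ENSGALG00000014634 was at 22.1 ± 8.33 FPKM (SD, n = 3) in black eyelids and at 2.09 ± 0.45 FPKM (SD, n = 3) in light-yellow eyelids, a ratio of 10.6. Its log2 difference was 2.85 (SE 0.29, 95% confidence interval 2.19 to 3.51), with a limma adjusted p of 0.0246. The recovered reads behind these values were 841, 956 and 1684 in the black-eyelid libraries and 112, 89 and 129 in the light-yellow ones. Novel02050 was at 6.42 ± 0.79 FPKM (SD, n = 3) in black eyelids and at 0.23 ± 0.099 FPKM (SD, n = 3) in light-yellow eyelids, a ratio of 27.8. Its log2 difference was 2.59 (SE 0.20, 95% confidence interval 2.12 to 3.06), with a limma adjusted p of 0.0145. It rested on 286, 299 and 337 reads in black eyelids and on 13, 6 and 14 reads in light-yellow eyelids.

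The remaining 2 loci that passed were non-Ensembl loci, each with a limma adjusted p of 0.0246. One was at 14.7 ± 2.01 FPKM (SD, n = 3) in black and at 2.94 ± 0.23 FPKM (SD, n = 3) in light-yellow eyelids, a log2 difference of 1.99 (SE 0.20). The other was at 5.02 ± 1.68 FPKM (SD, n = 3) in black eyelids, from 46 to 76 reads per library, and had 0 reads in all 3 light-yellow libraries. Against a floor of 3 reads in each light-yellow library, this was at least 21.2-fold higher in black eyelids. This bound covers counting error only.

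In the direction of light-yellow eyelids, the locus with the smallest p, ENSGALG00000023925, was at 84.8 ± 14.6 FPKM (SD, n = 3) there and at 21.7 ± 4.48 FPKM (SD, n = 3) in black eyelids. The ratio was 3.91 and the log2 difference, black minus light-yellow, was -1.92 (SE 0.22, 95% confidence interval -2.43 to -1.41). It did not pass with limma on log2(FPKM + 1), at an adjusted p of 0.0532. In limma's voom fits to the recovered reads it passed with library totals, at an adjusted p of 0.0399, and with quality weights, at 0.00594, but not with median-of-ratios size factors, at 0.0639. With limma on log2(FPKM + 1) it passed after quantile normalization, at an adjusted p of 0.0402, and with array quality weights, at 0.00341. Without black-eyelid bird 1 it passed at 0.0329, but not when any other bird was left out, at 0.0617 to 0.527. Novel00437, with the next smallest p in that direction, was at 9.98 ± 4.08 FPKM (SD, n = 3) in light-yellow and 1.501 ± 0.41 FPKM (SD, n = 3) in black eyelids, with a limma adjusted p of 0.196.

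**Figure D2:**
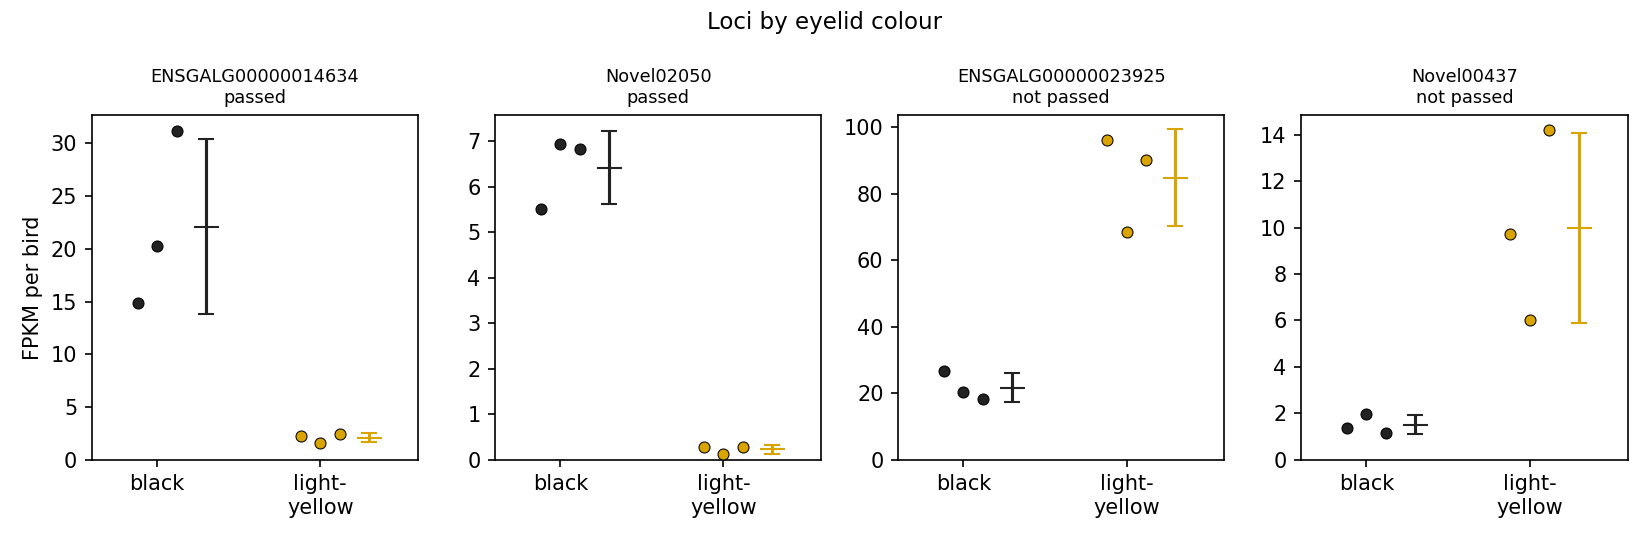
FPKM of 4 loci in each bird (points), by eyelid colour, with the mean and SD of the 3 birds beside them. The birds of the 2 colours do not overlap at any of the 4 loci, with ratios of 10.6 and 27.8 toward black at the 2 that passed, and of 3.91 and 6.65 toward light-yellow at the 2 that did not. The loci were chosen by difference or p in these same birds, so the lack of overlap is no separate evidence. Among all 13253 tested loci, 862 (6.50%) had no overlap, against 10% expected by chance.

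Which loci passed varied with the libraries used. Without black-eyelid bird 1 there were 9 loci past the threshold, 7 higher and 2 lower in black eyelids, including all 4. All 4 calls ended when any other bird was left out (limma adjusted p 0.0506 to 0.239). Without black-eyelid bird 2 there was 1 other locus, and 0 passed without black-eyelid bird 3 or light-yellow bird 1, 2 or 3. In the fits with 0, the loci at an unadjusted limma p under 0.05 numbered 204, 410, 245 and 296, in that order. With 1 bird left out, the log2 difference was between 2.58 and 3.09 for ENSGALG00000014634 and between 2.52 and 2.68 for Novel02050. Over all alternatives it ran from 2.58 to 3.47 and from 2.515 to 5.03, the highest values coming from the voom fit with quality weights. The call ended in 10 of 22 for ENSGALG00000014634, median-of-ratios rescaling among them (limma adjusted p 0.0562), and in 6 of 21 for Novel02050.

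The size of a difference did not decide which loci passed. On the log2(FPKM + 1) scale, the mean difference toward black of 6 loci was larger than that of ENSGALG00000014634, up to 4.18 (SE 1.42), and none passed with limma on log2(FPKM + 1) or with voom, the smallest unadjusted p being 0.000984. The largest difference toward light-yellow was -3.42 (SE 0.52), with a limma adjusted p of 0.224. Of the 95 loci at least 2-fold higher on average in black eyelids, 19 stood in a single bird at 10 times or more the level of every other bird. Of the 47 in the other direction, 1 did. The median standard error of a log2 difference was 0.24, so the median 95% confidence interval reached 0.56 to either side. In simulated data with the same depths and similar spreads, the test called 22% of the loci changed by 1 on the log2 scale. It called 80% of those changed by 2 and 96% of those changed by 3. The changed loci were drawn only from those above a floor of reads and an FPKM floor higher than the test's. These rates therefore do not cover the lowest tested loci. They also rest on 200 changed loci, since the Benjamini-Hochberg cut on p loosens as more loci pass. In the real data, with 4 loci past the threshold, the cut was stricter. There an unadjusted limma p of 2.01e-05, for ENSGALG00000023925, gave an adjusted p of 0.0532. For so few changed loci the rates would be lower, and this was not simulated. In this simulation, with 3 birds per colour, changes of 1 were mostly not called, and smaller ones were not simulated.

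By kind of identifier, of 1473 non-Ensembl loci tested, 22 were at least 2-fold apart with no overlap between the colours, 12 higher and 10 lower in black eyelids (1.49%). Of 11780 Ensembl loci, 24 were higher and 13 lower (0.314%). The ratio of these shares was 4.76. The share was also higher among non-Ensembl loci in 7 of the 9 other splits of the libraries, with a ratio of up to 3.85, and 10 splits are too few for a test. By abundance, 3 of the 4 loci that passed had a mean of 1 to 10 FPKM, among 5567 such loci, and 1 lay between 10 and 100 FPKM, among 6897. None of the 789 loci at 100 FPKM or more passed with limma or voom, and 46 of these had an unadjusted limma p under 0.05.

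No separation of the colours was detected in the expression profile as a whole. The mean Spearman correlation across loci was 0.945 between libraries of one colour and 0.949 between libraries of different colours, and 7 of the 10 splits gave a within-group excess as large as the real one (one-sided exact permutation p = 0.7, smallest possible 0.1). The closest pair, at 0.975, joined black-eyelid bird 1 and light-yellow bird 2. The most distant pair, at 0.915, was black-eyelid birds 1 and 3. The first principal component held 46.7% of the variance. Its scores were -34.3, 13.7 and 39.6 in black-eyelid birds 1, 2 and 3 and 28.1, -27.9 and -19.2 in light-yellow birds 1, 2 and 3 (two-sided exact permutation p = 0.8). The second held 20.8%, with scores of 0.84, 20.6 and 18.1 in the black-eyelid birds and -37.4, -3.93 and 1.73 in the light-yellow ones (two-sided exact permutation p = 0.2, adjusted p = 1 over 8 measures). With the first component of the variation within colours as a covariate, chosen after seeing the data, the same 4 loci passed. Such a covariate can change a standard error but not a log2 difference between the colours. This fit therefore does not show that the 4 loci are free of that variation.

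**Figure D3:**
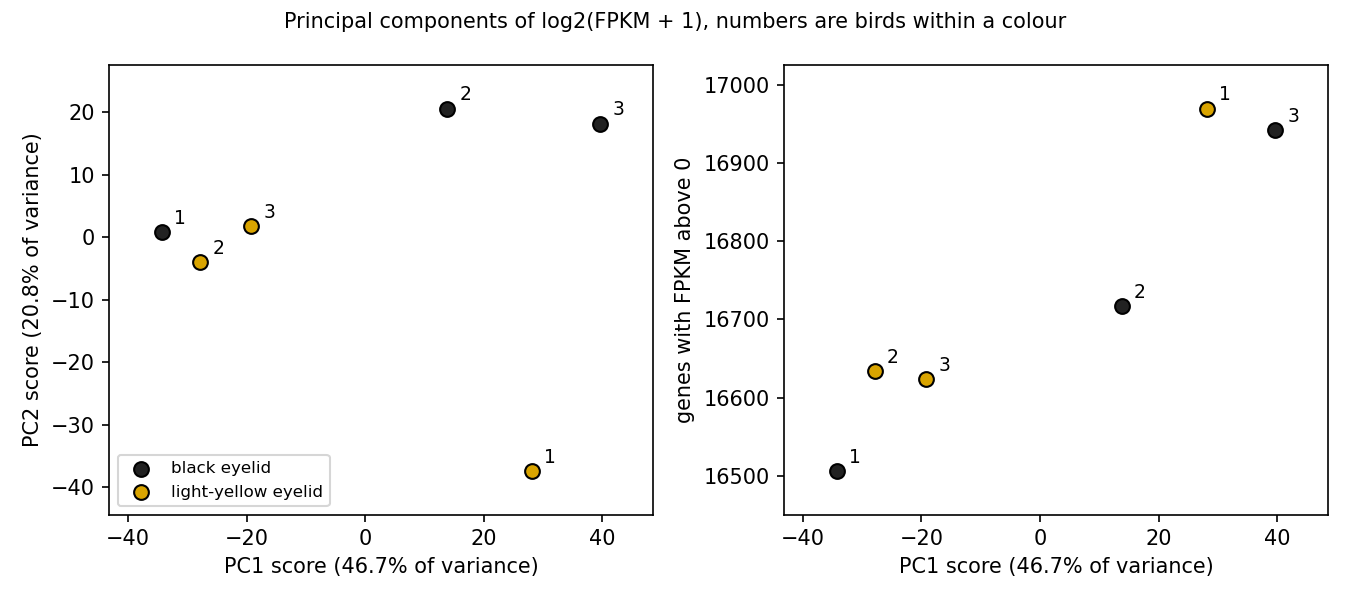
Left, scores of the 6 libraries on the first and second principal components of log2(FPKM + 1). Right, first component score against the number of loci above 0, from 16506 to 16970. Numbers are birds within a colour. Black-eyelid bird 1 lies with light-yellow birds 2 and 3 on the first component, which holds 46.7% of the variance.

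Library-wide measures did not differ detectably between the colours. The 100 most abundant loci took 33.8% ± 2.69 (SD, n = 3) of the summed FPKM in black and 37.5% ± 6.02 (SD, n = 3) in light-yellow eyelids (two-sided exact permutation p = 0.5, adjusted p = 1 over 8 measures). Light-yellow bird 1 had the highest share, 44.2%. Non-Ensembl loci took 6.51% ± 1.41 (SD, n = 3) in black and 6.36% ± 1.59 (SD, n = 3) in light-yellow eyelids (exact permutation p = 1, adjusted p = 1). With 3 birds against 3, these tests cannot go below 0.1.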

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

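Of the alternatives below, the voom fits and the covariate were chosen after seeing the data. Against 4 loci past the threshold, all higher in black eyelids, the same 4 passed with a pseudocount of 0.1 or 0.5, without a trend and with robust empirical Bayes. They also passed with a log2 difference of at least 1 required, which could remove none, since the smallest of their differences was 1.99. The same 4 passed with the first residual component as a covariate. Built from the variation within colours, it could change standard errors but no log2 difference. Without a filter 3 passed, 2 of them among the 4, after median-of-ratios rescaling 3, and after quantile normalization 5 (4 higher, 1 lower). At an adjusted p under 0.1 there were 6. With a filter at a mean of 5 FPKM, 0 loci passed, and 230 had an unadjusted limma p under 0.05. That filter left 2 of the 4 loci untested, and the other 2 had the same differences at an adjusted p of 0.0502. Array quality weights gave 13 loci (12 higher, 1 lower). On recovered reads, limma's voom called 7 loci (6 higher, 1 lower) with library totals and 8 (7 higher, 1 lower) with quality weights, each including the 4, but 3 with median-of-ratios size factors. Leaving out each bird in turn gave 0 to 9 loci, and at an unadjusted limma p under 0.05 between 204 and 1223. The 1 locus without black-eyelid bird 2 was none of the 4. Each such fit has fewer degrees of freedom. The fit with the bird number as a replicate block gave 0 loci (222 at an unadjusted limma p under 0.05). Birds with the same number deviated from their colour means with correlations of -0.51, -0.06 and -0.23. These values gave no sign that the numbers pair the birds, but they cannot exclude a smaller shared effect. No direction of the 4 named loci reversed in any alternative. Their birds do not overlap between the colours, so leaving out a bird or changing the pseudocount, filter or threshold could not reverse one. Over their alternatives the adjusted p of ENSGALG00000014634 ran from 0.0018 to 0.239 and that of Novel02050 from 0.0012 to 0.166. That of ENSGALG00000023925 ran from 0.00341 to 0.527. It passed in 6 of 22, which include the looser threshold of 0.1, where its limma adjusted p was still 0.0532. The planned gene list tests, their alternatives and the members of the lists were not run, for want of gene names. Depth limits loci of few reads, such as Novel02050 in light-yellow eyelids with 6 to 14.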

Other observations

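The tests of the non-Ensembl loci, of presence or absence and of chance splits were chosen after the result was seen. Black-eyelid bird 3 carried a set of transcripts of its own: 40 loci were at 1 FPKM or more and at 10 times or more the level of every other bird, up to 150 FPKM, and 6 of them were non-Ensembl loci. The corresponding number was 2 in black-eyelid bird 1, 0 in black-eyelid bird 2, and 0, 1 and 3 in light-yellow birds 1, 2 and 3. Across all birds, 44 tested loci spanned at least 4 on the log2(FPKM + 1) scale between the lowest and highest bird. In 7 of these the colours did not overlap, 6 higher and 1 lower in black eyelids, against 1 to 15 in the 9 other splits, and limma called none of the 44 between the colours (12 had an unadjusted p under 0.05, and voom called 0). In 17 of the 44, black-eyelid bird 3 alone was high.

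With 10 splits of the 6 libraries, no share under 0.05 is possible. The real split gave 4 loci and the highest other split gave 645, so 2 of the 10 splits gave as many as the real one. The remaining 8 gave 0. After median-of-ratios rescaling the highest split gave 1004, after a correction for length 855, and with voom 551. That highest split set black-eyelid bird 1 and light-yellow birds 2 and 3 against the others, and it points to a structure of the samples that crosses the colours. In it 274 loci were higher and 371 lower in the former 3 birds. Unequal read numbers alone are argued against, since 611 of the 645 loci were still called after all libraries were thinned to the shallowest. Thinning cannot remove a property of the libraries that goes with depth, so it does not speak to such a property. A shift by abundant loci is argued against as well, with 610 of them still called after median-of-ratios rescaling. Longer loci tended to be higher in the former 3 birds (Spearman rho 0.28 across loci, which are not independent), but 519 of the 645 were still called after each library's trend over length was removed, so length bias was not the whole cause. Of the library measures, some followed this split without overlap, which was noticed after it was found, and others did not (depth, the share of the 100 most abundant loci, the median FPKM). Loci above 0 numbered 16506, 16634 and 16624 in the former 3 birds against 16717, 16942 and 16970 in the others, and the share of recovered reads in non-Ensembl loci was 3.85%, 4.63% and 4.21% against 5.44%, 5.39% and 6.19%. These values do not tell a technical from a biological difference between the birds. RNA quality, dissection and cell composition stay open, and no biological explanation was tested, since the labels name no factor that follows this split.

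Non-Ensembl loci made up 3 of the 4 that passed and 11.1% of those tested. The hypothesis that they are over-represented among loci that differ by colour came from these same 4 loci, so a one-sided Fisher's exact test on them (p = 0.00503) is no independent evidence. The voom fit (3 of 7) holds the same 3. A different hypothesis, that non-Ensembl loci differ more between birds whatever the split, was not decided either. In 7 of the 9 other splits the share of loci at least 2-fold apart without overlap was also higher among non-Ensembl than among Ensembl loci, but in 0 of the 9 was the ratio of these shares as large as the real 4.76, the highest being 3.85. The 10 splits are too few to decide.

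No excess of presence or absence by colour was detected. Of 294 loci with a value above 0 in exactly 3 libraries, 13 were found in the 3 black-eyelid birds and 15 in the 3 light-yellow birds, against 14.7 expected for each (one-sided exact binomial p = 0.636 for both together). This test takes the loci as independent, which loci of the same libraries are not. Both directions together came to 28, against 29.4 expected, and by the same count the 9 other splits gave 12 to 63. Of the 13, 2 had at least 10 recovered reads in every black-eyelid library. Of the 15, 0 had as many in every light-yellow library.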
